A study of Mus musculus with 2 samples.

How the data were processed

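The mark measured was trimethylation of lysine 4 on histone H3 (H3K4me3), a chromatin mark found at the start sites of active and poised genes, by chromatin immunoprecipitation and sequencing (ChIP-seq). The tissue was the mouse facial prominences of embryonic day 10.5, the paired swellings of neural crest, mesoderm and epithelium that later fuse into the face. Per the labels, replicate 1 pooled tissue from 69 embryos of strain B6NCrl and replicate 2 pooled tissue from 51, both with male and female embryos mixed. The 2 replicates are biological replicates per the labels and form the only group, so no contrast between groups exists and every comparison is between replicates, regions or gene lists within this tissue.

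The authors deposited 4 peak lists in the narrowPeak layout on the mouse build mm10: 1 per replicate, 1 called on both replicates pooled, and 1 of peaks named replicated. Per the labels' file listing, the replicated list was derived from the pooled list and both replicates' own lists. The rule that made a peak replicated, the peak caller, the aligner and the calling thresholds are not given in the sources used here. The signal value that the authors deposited for each peak is the peak's own enrichment, in a unit not defined in the sources used here. It is the authors' value and was used to describe and rank peaks within their own list and, in 1 test, to match random lists on the highest signal of a domain. The −log10 q value of each peak was also deposited by the authors and served as a filter. Counts of reads are not part of these lists, so the depth of each library is unknown, and a difference in the number of peaks between lists can follow from depth. Confidence intervals of shares are exact Clopper-Pearson intervals at 95%, and they cover counting error over peaks only.

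Peaks on the 21 main chromosomes were used. Start sites were those of every annotated transcript in GENCODE release M21 on the same build, with 21938 protein-coding genes. A peak was placed at a promoter if it touched the window of 1 kb on either side of any annotated start site, otherwise in an exon, an intron or between genes. A gene was called marked if a replicated peak touched that window of any of its start sites. Replicated peaks separated by at most 1 kb were merged into domains, and the breadth of a gene was that of the longest domain at its start sites. A domain that covers several start sites counts for each of those genes, so its breadth does not belong to any of them alone. Near-identical gene copies, such as the adult alpha-globin pair Hba-a1 and Hba-a2, are uncertain, since the treatment of reads that map to both copies is not given in the sources used here.

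A peak of a replicate was called shared if the other replicate's peaks covered at least 50% of its length. The share was set beside 100 shuffles of the peak positions within chromosomes. The 13 gene lists were fixed before the data were examined, together with the tests, the settings and the rule for naming genes. Each list's share of marked genes was compared with all other protein-coding genes by a two-sided Fisher's exact test. Each list's median domain breadth was compared with 10000 random lists of as many start-site domains by a two-sided permutation test, for lists with at least 5 domains. The random lists drew on all 15273 domains at protein-coding start sites, while a gene list counted only the longest domain of each gene. A gene's shorter second domains thus entered mainly the random lists, which can raise the ratio of every list. The size of this effect was not measured. Both families of p-values were adjusted by the Benjamini-Hochberg procedure over the lists, with a threshold of 0.05. The smallest p that the permutations can give is 0.0002. Genes and domains are not independent replicates, so these tests describe the 2 libraries and not the spread between embryos. Values with an SD are the mean of the 2 replicates' own lists, processed in the same way.

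Genes were named by 5 criteria: the genes at the 12 broadest start-site domains, the 3 broadest and up to 3 unmarked members (in alphabetical order) of each list, the 3 genes per replicate with the highest signal among those marked in that replicate alone, the 5 broadest domains over 5 kb from any annotated start site, and a set of controls. The controls were Actb, Gapdh and the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y. For the Hox genes the number marked and the domains of each cluster were given as well.

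Alternatives were −log10 q of at least 2 or 5, windows of 250 bp or 2.5 kb, the pooled peaks, each replicate's list alone, the 5'-most start site of each gene only, merging of touching peaks only or across 2.5 kb, an overlap of 1 bp or 80%, and random lists matched on CpG content. The CpG content was the number of CpG dinucleotides within 500 bp of the start site, in 10 strata. Chosen after seeing the data were −log10 q of at least 10, replicated peaks that touch a peak of each replicate's own list, and domains at the start sites of 1 protein-coding gene only. The list tests were tested on simulated data with the real list sizes over all 21938 genes. For the share of marked genes, the Fisher test called 100% of 75 simulated lists planted at a share of 0.98, 100% of 60 planted at 0.3 and 0% of 60 planted at 0.7, near the genome-wide share. For breadth, the permutation test called 100% of 75 lists planted at 2 times the breadth, 87.9% of 58 planted at 0.5 times and 3.33% of 60 planted with no change. Each simulated gene had 1 domain of its own, so shared domains and second domains of a gene were not simulated. The 3.33% therefore does not cover their effect. Work was done in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. The domain of a gene is the longest at any of its annotated start sites, so it need not reach the 5'-most one, and among the genes whose breadth is given it did not come within 1 kb of that site at Egfl7, Esrrb, Hoxa3, Hoxb3, Hoxd3, Rara, Sftpc and Stk11. The 14 replicated peaks on unplaced scaffolds entered no comparison.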

Results

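H3K4me3 was mapped in the facial prominences of mouse embryos at day 10.5 in 2 biological replicates, pools of 69 and 51 embryos. Replicate 1 had 51407 peaks covering 54.7 Mb of the mm10 genome, with a median width of 459 bp, and replicate 2 had 38269 peaks covering 44.5 Mb, with a median width of 676 bp. The pooled list held 51661 peaks and the replicated list 32968 peaks covering 53.3 Mb, with a median width of 1164 bp. Of 32954 replicated peaks on the main chromosomes, 98.1% touched a peak of replicate 1, 87.3% a peak of replicate 2 and 85.8% a peak of both, so a gene marked in the replicated list need not have a peak in each replicate's own list. The depth of either library is unknown. Each pool carried H3K4me3 at the start sites of the housekeeping genes Actb and Gapdh, with domains of 7.93 ± 0.792 kb and 7.89 ± 1.31 kb (SD, n = 2), the latter 10.5 kb in the replicated list. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y were marked in both pools, with domains of 1.51 ± 0.221, 1.85 ± 0.247, 1.69 ± 0.0523 and 1.89 ± 0.129 kb (SD, n = 2). The labels give both sexes in each pool.

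The first comparison asked how far the pools of embryos gave the same marked regions. The protein-coding genes marked were nearly the same in both: 14860 genes had a start-site peak in each replicate, 309 in replicate 1 only and 55 in replicate 2 only. The share of protein-coding genes marked was 69.1% in replicate 1 and 68.0% in replicate 2, a mean of 68.6% ± 0.819 (SD, n = 2). Across genes marked in both, domain breadth was related between the replicates with a Spearman rho of 0.897, and the median ratio of breadth in replicate 1 to replicate 2 was 1.14. Single peaks were shared as follows. Of replicate 1 peaks, 51.9% (95% interval 51.5 to 52.3) had at least 50% of their length covered by replicate 2 peaks, against a mean of 1.85% for shuffled positions. Of replicate 2 peaks, 83.1% (82.7 to 83.5) were covered in this way by replicate 1 peaks, against 2.22% for shuffled positions. The 21208 replicate 1 peaks that touched no replicate 2 peak had a median width of 231 bp, against 1252 bp for the 30181 that did. Of these peaks that touched none, 22.5% lay at a start site, compared with 60.0% of those that did touch one. With −log10 q of at least 10, 99.4% of 21517 replicate 1 peaks and 99.99% of 19563 replicate 2 peaks touched a peak of the other replicate.

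**Figure D1:**
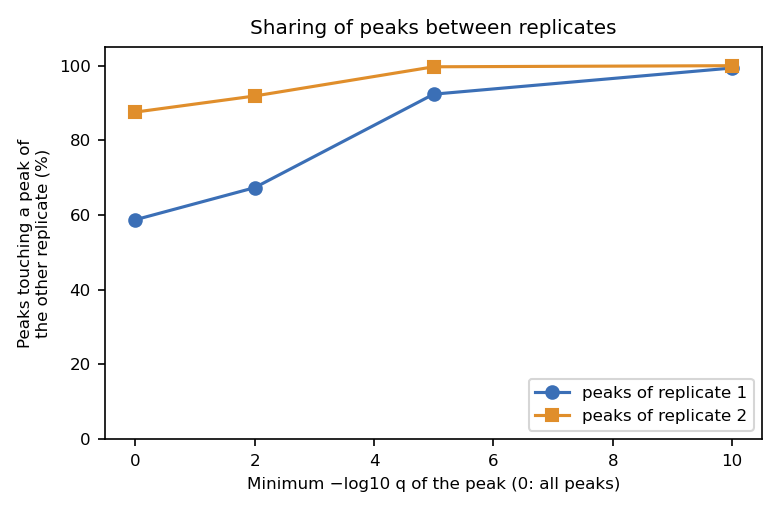
Percentage of each replicate's peaks that touch any peak of the other replicate (y axis), by the minimum −log10 q required of the peak (x axis); circles are replicate 1 and squares replicate 2. Replicate 1 rises from 58.7% of all peaks to 99.4% at the highest minimum, and replicate 2 from 87.6% to 99.99%.

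For the genes with the highest signal among those marked in 1 replicate alone, the other replicate had a peak nearby, outside the window of 1 kb. In replicate 1 they were Nup160, a nuclear pore gene on chromosome 2 (peak 90677997 to 90681071), Gm20538 on chromosome 19 and 4930415O20Rik on chromosome 15. The nearest replicate 2 peaks lay 1.07, 1.12 and 1.61 kb from these genes' start sites. In replicate 2 they were Tchh, which encodes the hair follicle protein trichohyalin, 4931409K22Rik and Vsig2. The nearest replicate 1 peaks lay 1.01, 1.42 and 2.14 kb from their start sites. The first 4 of these genes were marked in the replicated list, and 4931409K22Rik and Vsig2 were not. The replicated domains counted for Nup160, Gm20538, 4930415O20Rik and Tchh contained none of these genes' annotated start sites. They lay 0.836, 0.758, 0.723 and 0.957 kb from the 5'-most sites. Those of Gm20538 and 4930415O20Rik were shared with Ndufb8 and Ccnt1, respectively.

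The next question was where in the genome the mark lay. Replicated peaks were concentrated at start sites: 56.4% (95% interval 55.8 to 56.9) touched a promoter window, against 10.7% of shuffled positions. Introns held 17.7% of the peaks and intergenic sequence 18.3%, against 32.5% and 47.7% of shuffled positions, and exons held 7.65% against 9.13%. In the replicates' own lists, promoters held 44.5% of replicate 1 peaks and 52.6% of replicate 2 peaks. Of 21938 protein-coding genes, 14968 (68.2%) carried a replicated peak at a start site. The peaks formed 27563 domains, of which 15273 lay at protein-coding start sites with a median breadth of 2.43 kb, and 183 of those were broader than 10 kb. The number over 10 kb was 258 in replicate 1 alone, 98 in replicate 2 alone and 315 in the pooled peaks, and merging only touching peaks or merging across 2.5 kb gave 63 or 421.

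Among the 12 broadest start-site domains, the nuclear receptor gene Nr2f2 had a domain of 28.6 kb (chromosome 7, 70342833 to 70371415; 27.1 ± 1.76 kb, SD, n = 2) that covered the whole gene. The linked homeobox genes Dlx5 and Dlx6, which pattern the lower jaw, shared a domain of 28.2 kb (chromosome 6, 6854746 to 6882983), and Dlx1 and Dlx2, which act in the same branchial arches, shared 22.9 kb (chromosome 2, 71524567 to 71547417). The Dlx1 and Dlx2 domain was 23.2 ± 0.777 kb (SD, n = 2), while Dlx5 and Dlx6 were joined in replicate 2 (28.1 kb) but separate in replicate 1, at 9.47 and 18.1 kb. The T-box gene Tbx3 had 22.1 kb (chromosome 5, 119667524 to 119689624; 21.9 ± 0.0615 kb), the POU-domain gene Pou3f3 21.9 kb (chromosome 1, 42683996 to 42705943; 21.4 ± 0.394 kb) and the homeobox gene Six1 20.8 kb (chromosome 12, 73034600 to 73055402; 19.0 ± 3.15 kb). These domains covered Tbx3, Pou3f3 and Six1 from end to end. The Hedgehog receptor gene Ptch1 had a domain of 21.8 kb (chromosome 13, 63552564 to 63574359; 18.8 ± 3.72 kb) over 32.2% of its length. Bahcc1 had 25.2 kb (chromosome 11, 120218846 to 120244053; 22.4 ± 3.58 kb) and the transcription factor gene Ebf3 20.1 kb (chromosome 7, 137303242 to 137323344; 19.9 ± 4.47 kb). A domain of 21.2 kb on chromosome 2 (18038535 to 18059698, 18.2 ± 7.03 kb) lay within 1 kb of start sites of Skida1, Mllt10 and A930004D18Rik. It contained all 5 annotated start sites of Skida1, 1 of 11 of Mllt10 and 0 of 3 of A930004D18Rik. In replicate 2 no one domain joined these genes, and the longest at each were 13.2, 6.40 and 8.71 kb.

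The broadest domain of all was of another kind. It spanned 55.4 kb on chromosome 10 (80127497 to 80182904) at 7 closely spaced genes: Stk11, Cbarp, Atp5d, Midn, Cirbp, 1600002K03Rik and Efna2. Of the 8 annotated start sites of Stk11 it contained none and lay within 1 kb of 1, with the 5'-most site 11.7 kb away. It joined 18 peaks, and the longest domain that overlapped it measured 60.1 kb in replicate 1, where it extended beyond the replicated domain, and 35.0 kb in replicate 2. The domain of 35.0 kb did not reach Stk11, 1600002K03Rik and Efna2, where replicate 2 had 5.05, 3.01 and 3.29 kb.

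Craniofacial transcription factors, facial signalling genes, neuronal and placodal genes, endothelial genes, ribosomal protein genes and chromatin regulators mutated in facial syndromes were all marked without exception. The counts were 52 of 52, 47 of 47, 29 of 29, 24 of 24, 35 of 35 and 30 of 30, in each replicate as well as in the replicated list. Of 28 surface epithelium genes, 25 were marked. Against the other protein-coding genes, of which 68.2% were marked, Fisher's exact test gave adjusted p = 4.42e-08 for the craniofacial factors, 1.86e-07 for signalling, 5.09e-05 for neuronal genes, 0.000373 for endothelial genes and 0.0187 for surface epithelium. It gave 1.05e-05 for ribosomal proteins and 3.62e-05 for chromatin regulators. Random genes of the same CpG content were marked at 95.4% for the craniofacial list, 96.7% for signalling, 82.3% for surface epithelium, 99.0% for ribosomal proteins and 98.4% for chromatin regulators. Against these, the adjusted permutation p-values were 0.148, 0.395, 0.395, 1 and 1, so those calls ended. In all but the surface epithelium list every member was already marked, so no higher score was possible and these comparisons could not have passed. Neuronal and endothelial genes remained above their CpG-matched lists, which were marked at 80.1% and 66.0%, with an adjusted p of 0.000867 for each.

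Genes of adult organs, of blood and of the germline and pluripotent cells were marked less often than other genes. Of 35 adult organ genes 10 were marked (28.6%, adjusted p = 7.34e-06 by Fisher's exact test). The unmarked ones included Alb, Ambp and Apoa2, which encode plasma proteins made in the liver. Of 28 blood genes 12 were marked (42.9%, adjusted p = 0.0101 by the same exact test), and Alas2 of haem synthesis and the lymphocyte genes Cd3e and Cd79a were not. Of 25 germline and pluripotency genes 9 were marked (36.0%, adjusted p = 0.0016, exact test), with Asz1, Dppa2 and Dppa4 among the unmarked. Matched on CpG content, random lists were marked at 43.0% for adult organ genes (adjusted permutation p = 0.0515), 32.8% for blood genes (0.344) and 81.3% for germline and pluripotency genes (0.000867). The call was thus kept for germline genes and ended for the other lists, and for blood the direction turned, to a ratio of 1.31.

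Skeletal muscle genes and cartilage and bone genes did not differ from other genes in the share marked. Of 24 muscle genes 16 were marked (66.7%, adjusted p = 0.830 by Fisher's exact test). The marked members included the pharyngeal regulator Tbx1 at 10.8 ± 0.156 kb and the muscle precursor gene Lbx1 at 3.87 kb in the replicated list and 5.86 ± 2.48 kb in the replicates' own lists (SD, n = 2; 7.61 and 4.10 kb), and the contractile genes Acta1 and Myh3 and the acetylcholine receptor gene Chrna1 were unmarked. Of 25 cartilage and bone genes 16 were marked (64.0%, adjusted p = 0.725 by the exact test). Col2a1, the main collagen of cartilage, had a domain of 6.44 ± 0.0368 kb, Col1a2 3.59 ± 0.870 kb and Hapln1 3.29 ± 0.904 kb (SD, n = 2). The bone matrix genes Bglap and Dmp1 and the hypertrophic cartilage gene Col10a1 were unmarked.

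The lists also differed in domain breadth. The median domain of the craniofacial transcription factors was 11.3 kb over 50 domains, 4.63 times the median of random lists, and 10.3 ± 1.82 kb in the replicates' own lists (SD, n = 2). Facial signalling genes had a median of 5.13 kb (ratio 2.11), led by Ptch1, Wnt5a at 10.8 ± 1.97 kb and the retinoic acid receptor gene Rara at 11.5 ± 2.43 kb (SD, n = 2), where the domain lay at a downstream start site. Chromatin regulators had 4.49 kb (ratio 1.85), with the histone demethylase gene Kdm6b at 16.6 ± 1.26 kb, Arid1a at 9.61 ± 0.206 kb and Setd5 at 7.88 ± 1.70 kb. Neuronal and placodal genes had 4.08 kb (ratio 1.69), with the forebrain and eye regulators Six3, Foxg1 and Pax6 at 18.2 ± 3.32, 17.3 ± 5.66 and 14.5 ± 3.96 kb. Ribosomal protein genes had 3.94 kb (ratio 1.62), with the broadest domains at Rpl18, Rps15 and Rps18 (18.5 ± 13.2, 8.33 ± 3.81 and 9.37 ± 0.994 kb). In the replicated list these were 11.5, 11.3 and 10.2 kb and were shared with neighbouring genes. By the permutation test the adjusted p was 0.00052 for craniofacial, signalling, chromatin and ribosomal genes and 0.000867 for neuronal genes. All 5 calls held against CpG-matched lists, at ratios of 4.47, 1.87, 1.46, 1.504 and 1.78 in the order craniofacial, signalling, chromatin, ribosomal and neuronal.

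**Figure D2:**
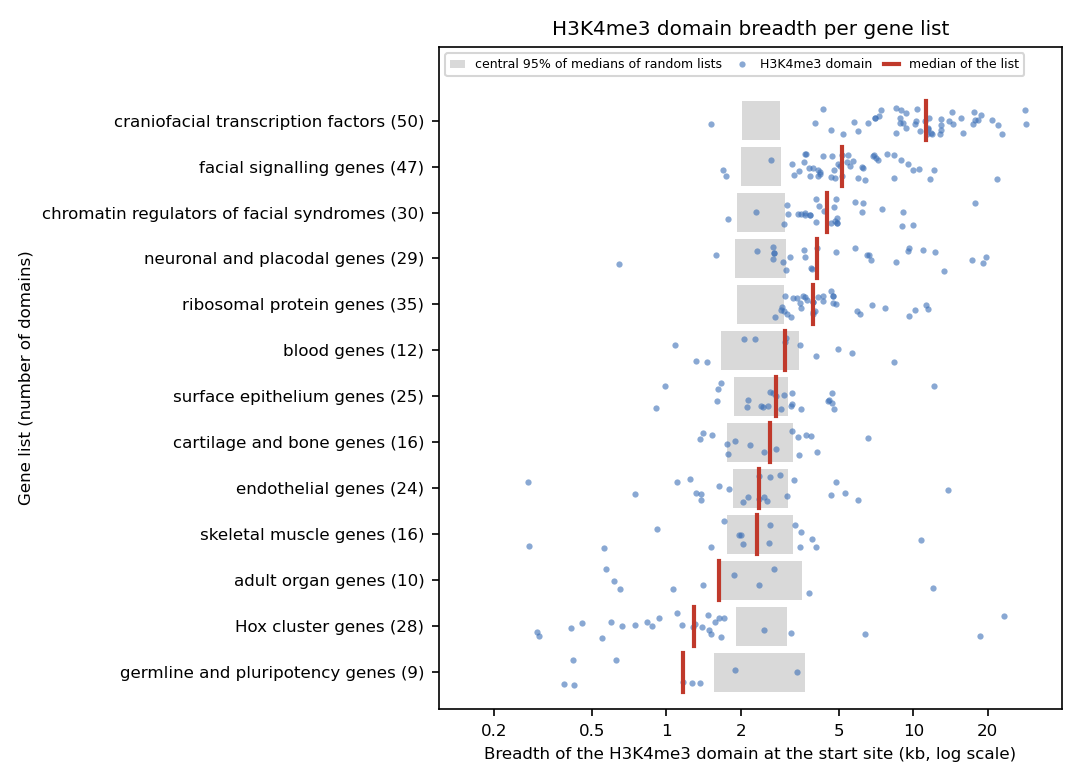
Breadth of each H3K4me3 domain at the start sites of 13 gene lists (x axis, kb, log scale; y axis, list with its number of domains). Points are domains, red lines the list medians and grey bars the central 95% of the medians of 10000 random lists; craniofacial transcription factors, at a median of 11.3 kb, lie farthest to the right of their grey bar (2.03 to 2.89 kb), and germline genes (1.17 kb) and Hox genes (1.29 kb) lie to the left of theirs.

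Lists of other cell types did not differ in breadth from random lists, with single broad members and exceptions under some settings. Surface epithelium genes had a median of 2.78 kb (ratio 1.14, adjusted p = 0.402 by permutation). Grhl3, a regulator of epidermal differentiation, had 4.77 ± 0.0912 kb and the simple-epithelium keratin Krt18 4.55 ± 0.000707 kb (SD, n = 2), and the tight-junction gene Cldn6 lay in a domain of 12.2 kb (8.92 ± 4.48 kb) with 4 neighbouring genes. The stratified-epithelium keratins Krt5, Krt14 and Krt15 were unmarked in the replicated list, although replicate 1 alone had peaks of 0.228 and 0.172 kb at Krt14 and Krt15. Endothelial genes had a median of 2.37 kb (ratio 0.976, adjusted permutation p = 0.847), with the transcription factor gene Fli1 at 13.3 ± 0.654 kb, Plvap at 5.95 ± 1.03 kb and Egfl7 at 5.64 ± 0.355 kb. Blood genes had 3.03 kb over 12 domains (ratio 1.24, adjusted permutation p = 0.310), with a median of 1.71 kb and a ratio below 1 in replicate 2 alone (0.804, adjusted p = 0.301). They were led by Lyl1 (8.61 ± 2.21 kb), Cd68 (5.57 ± 0.0290 kb) and Tal1 at 4.65 ± 0.444 kb. The domains at Lyl1 and Cd68 also lay within 1 kb of a start site of Nfix and Mpdu1, respectively. Against CpG-matched lists the endothelial median lay higher (ratio 1.37, adjusted permutation p = 0.0324), as did that of blood (ratio 1.69, adjusted p = 0.0137). Muscle genes had 2.32 kb (ratio 0.953, adjusted permutation p = 0.823), with Tcf21 at 4.02 kb in the replicated list and 1.36 ± 0.0410 kb in the replicates' own lists, and cartilage and bone genes had 2.64 kb (ratio 1.08, adjusted permutation p = 0.6998). The direction turned under some settings for the muscle, endothelial, blood, and cartilage and bone lists. In replicate 2 alone the muscle ratio was 0.626 (adjusted permutation p = 0.0237), and with merging across 2.5 kb the cartilage and bone ratio was 1.48 (0.0387).

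Germline and pluripotency genes had narrow domains, with a median of 1.17 kb over 9 domains (ratio 0.480, adjusted p = 0.0104 by permutation). Their broadest were at Prdm14 (2.29 ± 1.52 kb, and 3.38 kb in the replicated list), Esrrb (1.79 ± 0.0255 kb) and Tfcp2l1 (1.22 ± 0.172 kb; SD, n = 2 for each). The 10 domains of adult organ genes had a median of 1.64 kb (ratio 0.672, adjusted permutation p = 0.100). The broadest were at Nkx2-1, a regulator of thyroid, lung and ventral forebrain, at 12.1 kb (8.81 ± 4.68 kb), at Sftpc and at Cdx2. The domain counted for the surfactant gene Sftpc was shared with Bmp1. It contained 0 of the 2 annotated Sftpc start sites, lay within 1 kb of 1, and was 2.79 kb from the 5'-most site. The intestinal regulator Cdx2 had 2.74 kb in the replicated list but 2.57 kb in replicate 1 and 0.337 kb in replicate 2 (1.45 ± 1.58 kb). When only touching peaks were merged, the germline ratio was similar, at 0.533, but the call ended (adjusted permutation p = 0.0760). In the pooled peaks the ratio was 0.252 (adjusted permutation p = 0.00111). The adult organ list passed the threshold in replicate 2 alone (ratio 0.489, adjusted permutation p = 0.0201), with −log10 q of at least 5 (0.583, 0.0289) and with domains of 1 gene only (0.530, 0.0221).

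The Hox genes, which specify position along the body axis, carried the mark unevenly. Of 39 genes in the clusters, 31 were marked: 10 of 11 in Hoxa on chromosome 6, 8 of 10 in Hoxb on chromosome 11, 5 of 9 in Hoxc on chromosome 15 and 8 of 9 in Hoxd on chromosome 2. All 8 genes of paralogue groups 1 to 3 were marked, with a median breadth of 12.5 kb over genes. These genes lay at 6 distinct domains with a median of 4.04 kb, since 4 of them fell in 2 broad domains, and Hoxd3, Hoxd1, Hoxb1 and Hoxa3 had 6.36, 1.72, 1.64 and 0.548 kb. In groups 4 to 8, 13 of 15 were marked with a median of 1.30 kb, and in groups 9 to 13, 10 of 16 with 0.853 kb. A domain of 23.2 kb (52156811 to 52180045; 23.5 ± 0.446 kb, SD, n = 2) covered the start sites of Hoxa1, Hoxa2 and the neighbouring gene 5730596B20Rik. This domain also overlapped the 3' part of Hoxa3 (52169062 to 52213336, minus strand) but lay over 1 kb from each of that gene's 4 annotated start sites. The 0.548 kb domain given for Hoxa3 contained none of these sites and lay within 1 kb of 1. A domain of 18.7 kb (96336832 to 96355486) lay at Hoxb2 and Hoxb3. It contained 2 of the 4 annotated start sites of Hoxb3, both downstream of the 5'-most site, which lay 13.5 kb outside it, and the 6.36 kb domain of Hoxd3 likewise lay 22.7 kb from that gene's 5'-most site. The domain at Hoxb2 and Hoxb3 was 18.4 kb in replicate 2, and in replicate 1 it was 2 domains, of 10.1 kb at Hoxb3 and 7.33 kb at Hoxb2. Over the marked genes of groups 1 to 3, the median was 6.79 kb in replicate 1 and 18.4 kb in replicate 2. These medians cover different genes, since Hoxa3 had 0.24 kb in replicate 1 and no start-site peak in replicate 2. The replicated domain of Hoxa3 (52211630 to 52212177) nevertheless overlapped a replicate 2 domain (52211692 to 52211958), which lay outside the window of 1 kb. The replicate 1 domain at Hoxa3 (52213154 to 52213393) lay outside the replicated one. The longest domain of Hoxd was 6.36 kb and that of Hoxc 1.16 kb. Hoxa9, Hoxb6 and Hoxb9 were unmarked in the replicated list. Hoxa9 had a peak of 0.227 kb in replicate 1 alone, and Hoxb6 and Hoxb9 had peaks of 0.216 ± 0.00495 and 0.342 ± 0.0658 kb in the replicates' own lists (SD, n = 2). Hoxa3, Hoxa10 and Hoxa11, named after their values were seen, were marked in the replicated list with no start-site peak in replicate 2. The difference between paralogue groups was not tested.

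**Figure D3:**
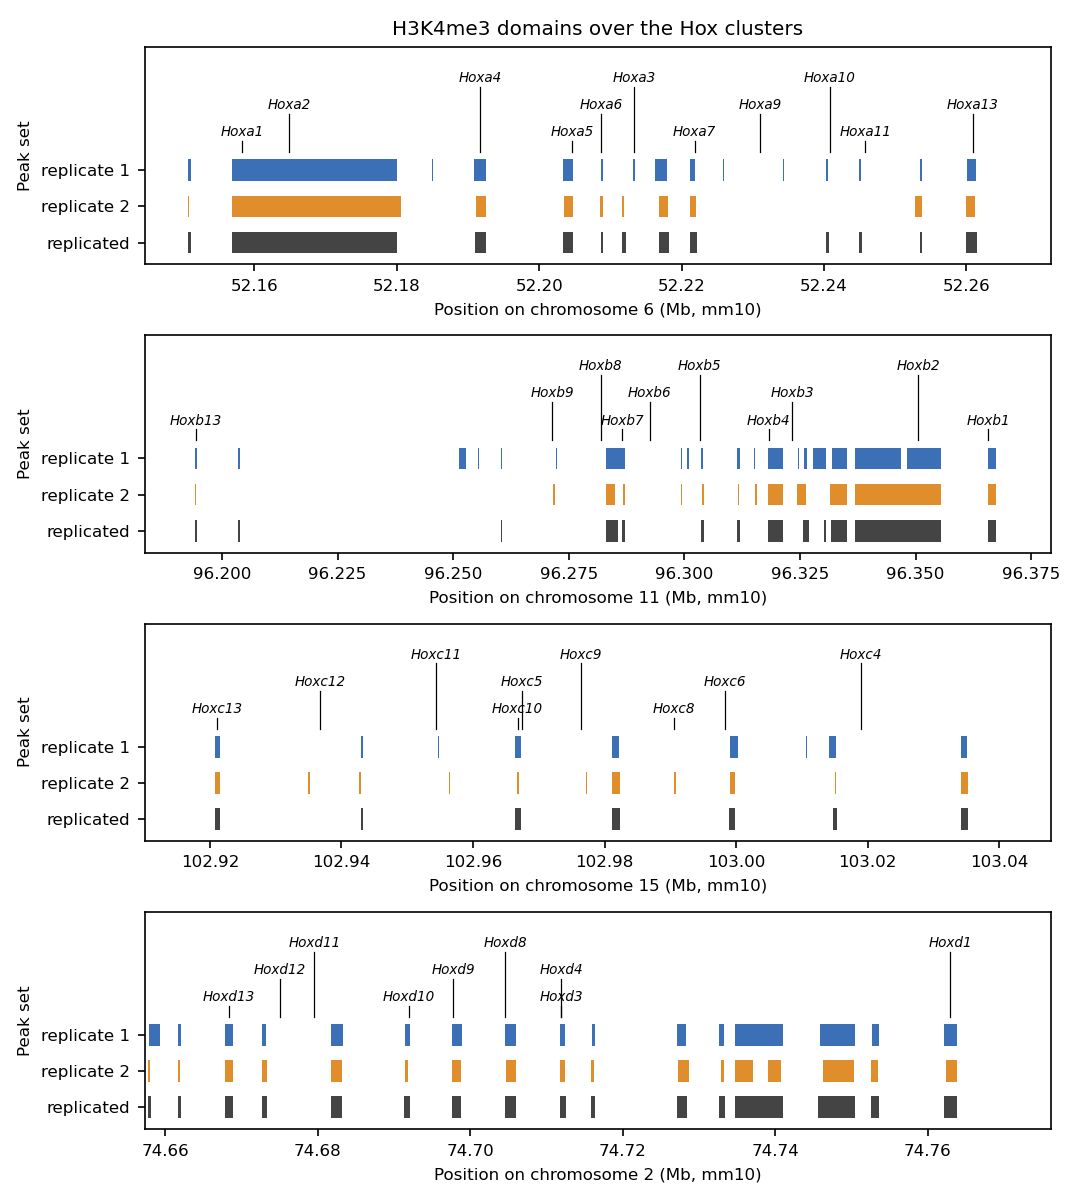
Maps of the Hoxa, Hoxb, Hoxc and Hoxd clusters (x axis, position in Mb on mm10; y axis, peak set). Bars are H3K4me3 domains of replicate 1, replicate 2 and the replicated list, and vertical lines mark the 5'-most annotated start site of each gene; the domain over Hoxa1 and Hoxa2 (23.2 kb) and that at Hoxb2 (18.7 kb) stand out from the narrow domains elsewhere.

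As a list, Hox genes did not differ from other genes in the share marked (79.5%, adjusted p = 0.198 by Fisher's exact test), and their median domain was narrow, at 1.29 kb (ratio 0.532, adjusted p = 0.00052 by permutation). Genes of the same CpG content were marked at 96.3%, above the Hox share (ratio 0.825, adjusted permutation p = 0.0013). In the pooled peaks and in replicate 1 alone, Hox genes were instead marked more often than other genes, at ratios of 1.41 (adjusted p = 4.95e-05 by Fisher's exact test) and 1.30 (adjusted p = 0.00612).

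Part of the mark lay away from any start site annotated in GENCODE. Of the 27563 domains, 7697 (27.9%) were over 5 kb from every start site, with a median of 0.692 kb, against 2.42 kb for all domains at start sites. The median signal of domains at start sites was 44.3, and that of these distant domains only 4.50. The broadest lay on chromosome 13 (23496979 to 23507992), 8.12 kb from the nearest GENCODE start site, that of Btn2a2, and measured 10.9 ± 0.000707 kb (SD, n = 2). Of the others, those on chromosome 19 (12004456 to 12013786) and chromosome 5 (125402603 to 125410876, between Dhx37 and Ubc) measured 9.06 ± 0.180 and 8.14 ± 0.177 kb. Another on chromosome 13 (21166131 to 21174231, 8.35 ± 0.504 kb) lay 5.21 kb from a start site of Trim27. The domain on chromosome 2 (115852441 to 115861289, 8.82 ± 0.0672 kb) lay 7.58 kb from an annotated start site of Meis2. That site lay near the 3' end of Meis2 (115863064 to 116065839, minus strand), far from the gene's 5'-most start site. Meis2 encodes a homeobox factor of the craniofacial list, and Ubc encodes a polyubiquitin. All of these 5 domains but the one near Meis2 had 5 to 7 transfer RNA (tRNA) genes of the RefSeq annotation within 1 kb.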

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

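Of the tests below, those of weak peaks, of GC content and of each Hox domain on its own were chosen after the result was seen. The comparison with CpG-matched lists was planned, but what it would show if CpG content were the cause was written down after its result. Outside the chromosomes used in the comparisons, 14 replicated peaks lay on 6 unplaced scaffolds, among them peaks within 1 kb of the genes Vamp7 and Tmlhe. They are listed here because no comparison used them. Peaks are expected where a scaffold carries annotated genes, but some of the 14 had no annotated gene within 1 kb.

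Replicate 1 had 21208 peaks that touched no replicate 2 peak. A different base composition was argued against, since the median GC content of these peaks minus that of peaks touching replicate 2 was -0.192 percentage points. Weak peaks near the calling threshold remain a possible explanation: among replicate 1 peaks with −log10 q of at least 10, 99.4% touched a replicate 2 peak. A spread of signal around marked sites stays possible as well. Of the peaks that touched none, 67.1% lay within 5 kb of a domain of touching peaks, 5.43 times the 12.4% of shuffled positions. The strength of those domains was not used. Shuffled positions ignore the preference of peaks for start sites, so the comparison cannot tell spread from clustering near the same genes. Depth was not given, and no biological explanation was tested, since the labels name no difference between the pools beyond the number of embryos.

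The domains at Hoxa1 and Hoxa2 and at Hoxb2 and Hoxb3 stood apart from other Hox genes. At Hoxa2, a single pool of embryos and the merging of separate peaks were both argued against, as the narrower replicate had 23.2 kb and touching peaks alone gave 16.3 kb. At Hoxb3, merging cannot be excluded, as touching peaks alone gave 9.01 kb. For a single pool the set test could not decide, with 10.1 kb in the narrower replicate against an SD of 5.89 kb. Replicate 1 had domains from 96336825 to 96346918 and from 96348121 to 96355450, and replicate 2 had 1 from 96337002 to 96355419. Both pools thus carried the mark over most of this stretch, which argues against a mark from a single pool. Only in replicate 2 was it 1 joined domain. That the Hoxa domain is a feature of this tissue stays a hypothesis, and no biological explanation was tested.

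The breadth of domains at craniofacial transcription factors was weighed against what sets breadth elsewhere. Their median was 4.47 times that of CpG-matched lists, 4.76 times that of lists matched on the highest signal in the domain (central 95% of those lists 2.05 to 2.79 kb), and 2.52 times that of lists drawn from 177 domains of other homeobox, Fox, Sox, T-box and Zic genes (3.55 to 5.50 kb). The first 2 comparisons argue against CpG content or strength of the mark as the whole cause. The third shows only that the list was broader than that pool, which left out the Hox genes. It cannot set aside the class of transcription factor, since the craniofacial list also holds families absent from the pool, such as Nr2f, Tfap2, Hand and Twist. Mixed cells stay open and untested, since a broad domain may be the sum of narrower ones in different cells of the tissue. That the breadth reflects the identity of the facial tissue is therefore a hypothesis, with no other tissue to compare.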

How the results depend on the processing

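Peaks with −log10 q of at least 10, replicated peaks touching both replicates' own peaks, and domains of 1 gene were chosen as alternatives after the data were seen, as was the count of start-site domains over 10 kb. The breadth calls for craniofacial (ratio 3.90 to 5.14), signalling (1.87 to 2.26), chromatin (1.46 to 2.00), ribosomal (1.504 to 1.92), neuronal (1.43 to 2.29) and Hox genes (0.389 to 0.575) kept their direction and stayed past the threshold under all 13 alternatives, as did the marked shares of neuronal, endothelial and germline genes under all 10. For the named genes, 556 of the recomputed breadths stayed within the SD of the replicates, some with no change, and 168 moved by more. For Nup160, Gm20538, 4930415O20Rik and Tchh, which had no SD, any change was counted among the latter. Genes that share a domain were each counted. No paired analysis was possible because there is a single group. Depth is unknown, so its effect could not be measured. The cause of the changes below was not tested, beyond the stricter threshold, which removes peaks by construction.

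With −log10 q of at least 5, the lists held 27191 (replicate 1), 23086 (replicate 2) and 29795 (pooled) peaks. Shared peaks with −log10 q of at least 2, 5 and 10 made up 58.3%, 78.0% and 88.0% of replicate 1 and 87.0%, 97.4% and 99.2% of replicate 2. With an overlap of 1 bp the shares were 58.7% and 87.6%, and with 80% they were 37.2% and 74.7%. Peaks at promoters made up 65.6% with the window of 2.5 kb, 43.9% of pooled peaks and 44.5% to 52.6% in the single replicates. Genes marked made up 67.3% and 69.1% with windows of 250 bp and 2.5 kb, 69.4% with pooled peaks, 64.8% with the 5'-most start site and 68.0% to 69.1% in the single replicates.

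Start-site domains over 10 kb numbered 183, against 315 with pooled peaks, 98 to 258 in the single replicates, 63 with touching peaks only and 421 with merging across 2.5 kb. Under the other 6 alternatives the count stayed within 1.5 times of this.

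For the share of a list marked, CpG-matched lists gave ratios of 1.05 (craniofacial), 0.825 (Hox), 1.03 (signalling), 1.08 (surface epithelium), 1.27 (muscle), 1.31 (blood), 1.14 (cartilage and bone), 0.665 (adult organ), 1.01 (ribosomal) and 1.02 (chromatin). Craniofacial, signalling, ribosomal and chromatin genes, all marked, could not have scored higher there. The Hox ratio was 1.41 with pooled peaks and 1.21 to 1.30 in the single replicates. The muscle ratio was 1.08 with the window of 2.5 kb and 0.919 to 1.02 in the single replicates. Surface epithelium fell to 1.27 (adjusted p = 0.0946 by Fisher's exact test) with the 5'-most start site.

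For breadth, the single replicates gave ratios of 0.626 to 0.867 (muscle), 1.01 to 1.08 (endothelial), 0.804 to 1.45 (blood), 0.984 to 1.22 (cartilage and bone) and 0.489 to 0.686 (adult organ). With −log10 q of at least 5 the ratio was 0.930 for blood, 0.906 for cartilage and bone and 0.583 for adult organ genes (a gained call, adjusted permutation p = 0.0289). Muscle turned to 1.05 with the window of 250 bp, 1.10 with pooled peaks and 1.16 with CpG-matched lists. Endothelial genes turned to 1.01 with the window of 2.5 kb, 1.11 with pooled peaks, 1.37 with CpG-matched lists and 1.02 with domains of 1 gene, which gave 0.530 for adult organ genes (gained, adjusted permutation p = 0.0221). Blood gave 0.945 with peaks touching both replicates' peaks, 0.885 with touching peaks only and 1.69 with CpG-matched lists. Cartilage and bone gave 0.975 with the 5'-most start site, 0.964 with peaks touching both replicates' peaks, 0.942 with touching peaks only and 1.48 with merging across 2.5 kb (gained, adjusted permutation p = 0.0387). Germline genes gave 0.533 with touching peaks only.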

Other observations

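The groups in this part were chosen after the data were seen, while both tests of the distant domains were set before their results were. Sensory receptor genes were almost devoid of the mark: 3 of 1135 olfactory receptor genes and 1 of 331 vomeronasal receptor genes had a replicated start-site peak, as did 0 of 42 beta-defensin genes and 1 of 57 keratin-associated protein genes. Clustered protocadherin genes were marked at 24 of 57. Of families of developmental regulators, marked members were 19 of 19 Sox genes, 6 of 6 genes of the Six1 to Six6 series, 8 of 8 Lhx genes, 8 of 9 Pax genes, 40 of 44 Fox genes, 19 of 19 Wnt genes and 20 of 22 Fgf genes. The median domain was 12.9 kb for Six1 to Six6, 9.04 kb for Pax, 8.46 kb for Lhx, 6.76 kb for Sox and 4.47 kb for Fox genes, and 3.12 kb for Wnt and 2.68 kb for Fgf genes. Zinc finger genes of the Zfp series were marked at 350 of 394 with a median of 2.32 kb, and histone genes at 61 of 67 with 5.38 kb. The median number of CpG dinucleotides near the start site was 5 for olfactory and 4 for vomeronasal receptors, against 64 to 78.5 for the families of developmental regulators, and genes rich in CpG were nearly all marked in the CpG-matched lists, so no difference beyond CpG content was shown. Some of these genes are also members of the fixed lists.

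Among genes that do not encode proteins, the mark was present at 180 of 190 long RNAs annotated at bidirectional promoters, 1177 of 2959 antisense genes, 1097 of 5854 intergenic long RNAs, 408 of 2202 microRNA genes and 277 of 9940 processed pseudogenes. The start sites of antisense and bidirectional genes often lie close to those of coding genes, so the mark cannot be assigned to either. The same limit holds for any microRNA gene or other gene whose annotated start lies close to that of another gene.

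The 7697 domains far from GENCODE start sites were set against the RefSeq annotation. RefSeq start sites lay within 1 kb of 8.77% of them, against 1.41% of shuffled positions. This argues against start sites that only RefSeq annotates as the main source over all of them, while sites missing from both annotations could not be seen. Among the 145 distant domains over 3 kb, the share near a RefSeq start site was higher, at 43 (29.7%). The hypothesis that transfer RNA genes, which another RNA polymerase transcribes, account for part of them was tested next: 61 of the domains (0.793%) lay within 1 kb of a tRNA gene, against 0.0224% of shuffled positions. The enrichment was 35.5 times, but the share was below the 1% set in advance, so tRNA genes may explain a small part only. Of those 145 broader domains, 18 lay near a tRNA gene, and of the 5 broadest, those on chromosome 13 (6 and 7 tRNA genes), chromosome 19 (7) and chromosome 5 (5) did, while the one near Meis2 had none. The domain on chromosome 19 and the one near Trim27 on chromosome 13 each also had 1 RefSeq start site within 1 kb. Of 403 tRNA genes in RefSeq, 273 (67.7%) lay within 1 kb of a replicated peak.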
